A study of Mus musculus with 9 samples.

How the data were processed

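RNA was measured by sequencing in 9 libraries of mouse regulatory T cells, in 3 groups of 3: synovium of arthritic mice, draining lymph node of arthritic mice, and draining lymph node of control mice. Per the labels' protocols, paws and nodes were digested, the cells were sorted on a Foxp3 reporter (YFP), RNA was extracted with Trizol, and libraries were made with a directional kit. Groups and replicate numbers came from the sample titles, which number separate mice. The synovial and node libraries of arthritic mice carry the same mouse numbers and were read as coming from the same animals.

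The submitters' processing notes name HISAT2 (an aligner), HTSeq (a read counter), DESeq2 and the mm10 genome. Versions, the annotation and the strand setting of the counting were not given in the sources used here. The deposited expression table holds a normalized signal for 23420 genes, which are gene read counts divided by a size factor per library. This was checked on the values: 100% of the nonzero values in each library were whole multiples, within 0.01, of a constant, and the constants matched DESeq2 size factors recomputed from the recovered reads. The division puts libraries on a common scale under the assumption that most genes do not differ. The recovered reads numbered 11300406 to 12855435 per library, and 3 reads, the floor used for genes at 0, corresponded to normalized values of 2.61 to 3.52. Intervals and floors cover counting error only, because reads were not counted as molecules.

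A table of the authors' own comparison was deposited too. Its columns give a mean normalized signal over libraries, log2 fold changes and their errors on the log2 scale, a test score (the Wald statistic), and p-values with adjusted p-values, per the file headers. The table's direction was settled by a rerun: DESeq2 on the recovered reads of the 6 libraries of arthritic mice gave synovial over node log2 fold changes within 1.4e-06 of the deposited ones.

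The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(normalized value + 1). The 11357 genes with a mean of 10 or more over the 9 libraries were tested. All 9 libraries entered each fit and shared an estimate of the spread. Tests were two-sided with Benjamini-Hochberg (BH) adjustment over all genes tested, and genes with an adjusted p under 0.05 were called changed. Fold changes are differences of mean log2(value + 1). The added 1 lowers the change of low genes, but a library at 0 beside others with reads can raise it. Atf3, for example, was 353-fold higher in synovium than in arthritic nodes on this scale, against a ratio of means of 156. Where a group had no read, a fold is given as a lower bound against 3 reads per library, and with 1 to 3 reads as a ratio with a 95% counting interval. Comparisons were synovial against node Tregs of arthritic mice, node Tregs of arthritic against control mice, and synovial Tregs against control node Tregs.

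Before the data were examined, 31 gene lists with 496 distinct genes were fixed, 19 of programs and 12 of markers of other cells. Some lists share genes, such as Il10, Areg and Gzmb in the effector and suppressive lists, so their results are not independent. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with BH adjustment over the lists of a comparison. The mitochondrially encoded list was not analysed here. The rule for named genes was fixed at the same time. For the tissue and disease comparisons it took up to 10 genes per direction with the largest log2 fold change among called genes with a mean of 50 or more in the higher group and no overlap of the groups' libraries. For the comparison differing in both it took 5 per direction. Predicted genes, pseudogenes and antigen receptor segments were left out of the rule, and members of the fixed lists could be named as well. Some genes that these rules allow are not reported here, though they are in the counts and list tests. Positions came from GENCODE vM21 on GRCm38, the assembly also called mm10.

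Alternatives changed the pseudocount (0.5 or 5), the filter (none, or a mean of 50), the variance model (no trend, or weights per library), the libraries in the fit (only the 2 groups compared), the scaling (TMM or quantile), the test (edgeR 4.0.16 quasi-likelihood or DESeq2 1.42.0 on recovered reads), the threshold (at least 2-fold), the mouse number as a block, and each library left out in turn. Lists were also tested with an estimated correlation and with fry. Fits with the block held only the libraries of the 2 groups compared. In the tissue comparison the mouse number pairs the libraries by the titles. The residuals of same-numbered libraries correlated across genes at 0.02, 0.05 and 0.09, and each library correlated best with its own number in 3 of 3 pairs.

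The scripts were tested on simulated counts with 200 genes changed by known folds. For the tissue comparison, limma recovered 41.7% of 2-fold and 76.3% of 4-fold changes over 11288 genes, with 7 false among 121 calls. For the disease comparison it recovered 35.4% and 76.5% over 11316 genes, with 9 false among 118 calls. For the comparison differing in both it recovered 45.9% and 73.5% over 11324 genes, with 8 false among 125 calls. DESeq2 recovered 52% of 2-fold changes in the disease simulation, with 32 false among 167 calls. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom between their reads was 18.9 or more.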

Results

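Regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses, were profiled by RNA sequencing in collagen-induced arthritis, a mouse model of inflammatory joint disease. The 9 libraries comprised 3 of synovial Tregs from arthritic mice, 3 of Tregs from the draining lymph nodes of arthritic mice, and 3 of Tregs from the draining nodes of control mice. Each held 11300406 to 12855435 reads assigned to genes, and 11770 to 13118 genes had at least 1 read. Values are normalized read counts, given as mean ± SD of 3 libraries, and fold changes are log2 ± standard error from limma with Benjamini-Hochberg adjusted p-values. Replicates correlated across genes at r = 0.910 to 0.946 on the log2 scale. The leading principal component held 53.1% of the variance and separated synovial from node libraries. Control node library 1 lay at 83.5 on the next component, which held 10.9%, against -41.4 to 18.8 for the other libraries.

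The tissue comparison asked how Tregs in the inflamed joint differed from those in the node draining it. Synovial Tregs had higher levels of genes known from effector and tissue Tregs. Gata3, a transcription factor of tissue Tregs, averaged 34099 ± 5737 in synovium and 6521 ± 1168 in arthritic nodes, a rise of 2.39 ± 0.15 (adjusted p = 1.73e-07). Il1rl1, the IL-33 receptor, averaged 16383 ± 5122 against 1091 ± 341 and rose by 3.91 ± 0.39 (adjusted p = 1.17e-05). Areg, which encodes the growth factor amphiregulin, averaged 3818 ± 647 against 50.2 ± 20.9 and rose by 6.31 ± 0.61 (adjusted p = 8.6e-06). Control node Tregs averaged 6464 ± 479 for Gata3, 354 ± 240.0 for Il1rl1 and 14 ± 9.89 for Areg.

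All 24 measured genes of the effector and tissue Treg list rose, 24 also when adjusted over the list alone, with a median of 3.18. The chemokine receptor Ccr8 rose by 3.71 ± 0.26, the costimulatory receptor Tnfrsf9 by 4.25 ± 0.21 and Klrg1 by 3.22 ± 0.51. Camera gave the list an adjusted p = 4.75e-14, and an adjusted p = 0.0545 with an estimated correlation. Of 16 Treg core genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 3.96e-05, and adjusted p = 0.0946 with an estimated correlation). Il2ra, the high-affinity IL-2 receptor chain, rose by 1.74 ± 0.12 and Ctla4 by 1.83 ± 0.15, while Gpr83 fell by 3.48 (SE 0.18). Foxp3 itself averaged 465 ± 65.3 in synovium, 269 ± 41 in arthritic nodes and 266 ± 123 in control nodes. Its difference of 0.79 ± 0.30 did not pass (adjusted p = 0.0597), but did in a fit of the 2 arthritic groups alone with the mouse number as a block (adjusted p = 0.0232). Foxp3 lies on chromosome X from 7573644 to 7595245 (GRCm38), where its exons overlap Flicr on the same strand and Ccdc22 on the other, so its reads are uncertain.

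Of 17 suppressive effector molecules, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.54e-07). The cytokine gene Il10 averaged 2175 ± 631 in synovium against 260.1 ± 162 in arthritic nodes, a rise of 3.31 ± 0.48 (adjusted p = 0.000225). Fgl2 rose by 3.67 ± 0.36 and the decoy receptor Il1r2 by 2.98 ± 0.38, while perforin, Prf1, fell by 3.20 (SE 0.34). Of 14 TNF receptor superfamily genes, 9 rose and 1, Tnfrsf26, fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000597, and adjusted p = 0.0722 with an estimated correlation). Tnfrsf4, which encodes OX40, rose from 11324 ± 815 to 66783 ± 5433 (2.56 ± 0.10, adjusted p = 5.49e-09), and Tnfrsf18 rose by 1.74 ± 0.10.

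Genes of NF-kB signalling rose together: 17 of 18 passed, 17 also adjusted over the list alone, with a median of 1.83 (camera adjusted p = 1.77e-12). Tnfaip3, a feedback inhibitor of the pathway, averaged 29572 ± 4390.0 against 1759 ± 148 (4.06 ± 0.12, adjusted p = 3.2e-09), Rel rose by 3.93 ± 0.15 and Nfkbia by 2.22 ± 0.15. The difference for Cflar was 0.10 ± 0.17 (adjusted p = 0.683). Of 18 genes of the antigen receptor response, 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.000473, and adjusted p = 0.0574 with an estimated correlation). Nr4a1 rose by 3.42 ± 0.18, while Egr2 fell by 1.57 (SE 0.24) and Myc fell by 0.75 (SE 0.15).

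Of 21 chemokine receptor and adhesion genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 4.29e-06, and adjusted p = 0.134 with an estimated correlation). Cxcr6 rose by 3.73 ± 0.40, Ccr1 by 5.39 ± 0.93 and the integrin gene Itgav by 4.34 ± 0.15. Of 14 Th17 genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 7.84e-06, and adjusted p = 0.0574 with an estimated correlation). Il23r rose by 4.41 ± 0.75, and Il17a averaged 131 ± 35.1 in synovium with no read in the 6 node libraries. Of 15 Th1 genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 7.16e-05, and adjusted p = 0.0574 with an estimated correlation). Stat4 rose by 1.93 ± 0.12 and Ifng by 1.76 ± 0.39. Tbx21 differed by 1.98 ± 0.74 (adjusted p = 0.058), and passed in a fit of the 2 arthritic groups alone with the mouse number as a block (adjusted p = 0.00546).

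Genes of naive and node-homing T cells were lower in synovium. Of 18, 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -2.33 (camera adjusted p = 1.67e-07). Tcf7, a transcription factor of naive and memory T cells, averaged 549 ± 223 in synovium against 4031 ± 52.7 in arthritic nodes and fell by 2.97 (SE 0.25, adjusted p = 2.64e-06). The survival gene Bcl2 fell by 3.20 (SE 0.11), while the IL-7 receptor gene Il7r rose by 1.33 ± 0.21. Of 11 follicular T cell genes, 2 rose (Bcl6 and Pdcd1) and 6 fell, among them Slamf6 and Il6ra (2 and 6 adjusted over the list alone; camera adjusted p = 0.444).

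Of 22 type I interferon response genes, 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 7.16e-05, and adjusted p = 0.41 with an estimated correlation). Usp18 averaged 292 ± 103 in synovium against 2479 ± 383 in arthritic nodes and fell by 3.12 (SE 0.30, adjusted p = 7.61e-06), and Ifit2 fell by 1.97 (SE 0.21). Isg15 differed by 0.45 ± 0.31 (adjusted p = 0.292). Of 21 interferon gamma response genes, 3 rose and 9 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.139). Gbp2 fell by 1.07 (SE 0.17) and Cd274, which encodes PD-L1, rose by 1.87 ± 0.25.

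Of 21 glycolysis and hypoxia genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 9.49e-05, and adjusted p = 0.176 with an estimated correlation). Hif1a rose by 2.55 ± 0.14 and hexokinase 2, Hk2, by 3.61 ± 0.54, while Pdk1 fell by 1.71 (SE 0.16). Of 17 cholesterol synthesis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.231), with Cyp51 up by 1.70 ± 0.19. Of 17 fatty acid genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.52), with Scd2 down by a log2 change of -2.08. Of 28 cell cycle genes, 2 rose (Cenpa and Pcna) and 2 fell (Mcm2 and Plk1), with 1 and 0 adjusted over the list alone (camera adjusted p = 0.665). Mcm2 did not pass without synovial library 1 (adjusted p = 0.0562) or 2 (0.0548) or arthritic node library 2 (0.0608) or 3 (0.097). The same held for Pcna without synovial library 1 (adjusted p = 0.117) or arthritic node library 2 (0.109) or 3 (0.0681), and for Plk1 without synovial library 2 (adjusted p = 0.128) or arthritic node library 1 (0.0579), 2 (0.121) or 3 (0.133). The proliferation marker Mki67 differed by 0.39 ± 0.46 (adjusted p = 0.545).

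Heat shock and immediate-early genes were higher in synovium: 22 of 25 dissociation and stress genes rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 1.76 (camera adjusted p = 5.13e-12). Dusp1 averaged 40768 ± 1632 against 3366 ± 842 and rose by 3.62 ± 0.19. Fos averaged 9503 ± 7145 against 268 ± 168 and rose by 5.19 ± 1.00 (adjusted p = 0.00167), and Jun differed by 1.87 ± 0.93 (adjusted p = 0.145). Joint and node differed in tissue and in the sample digested, so this group of genes cannot be assigned to either.

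**Figure D1:**
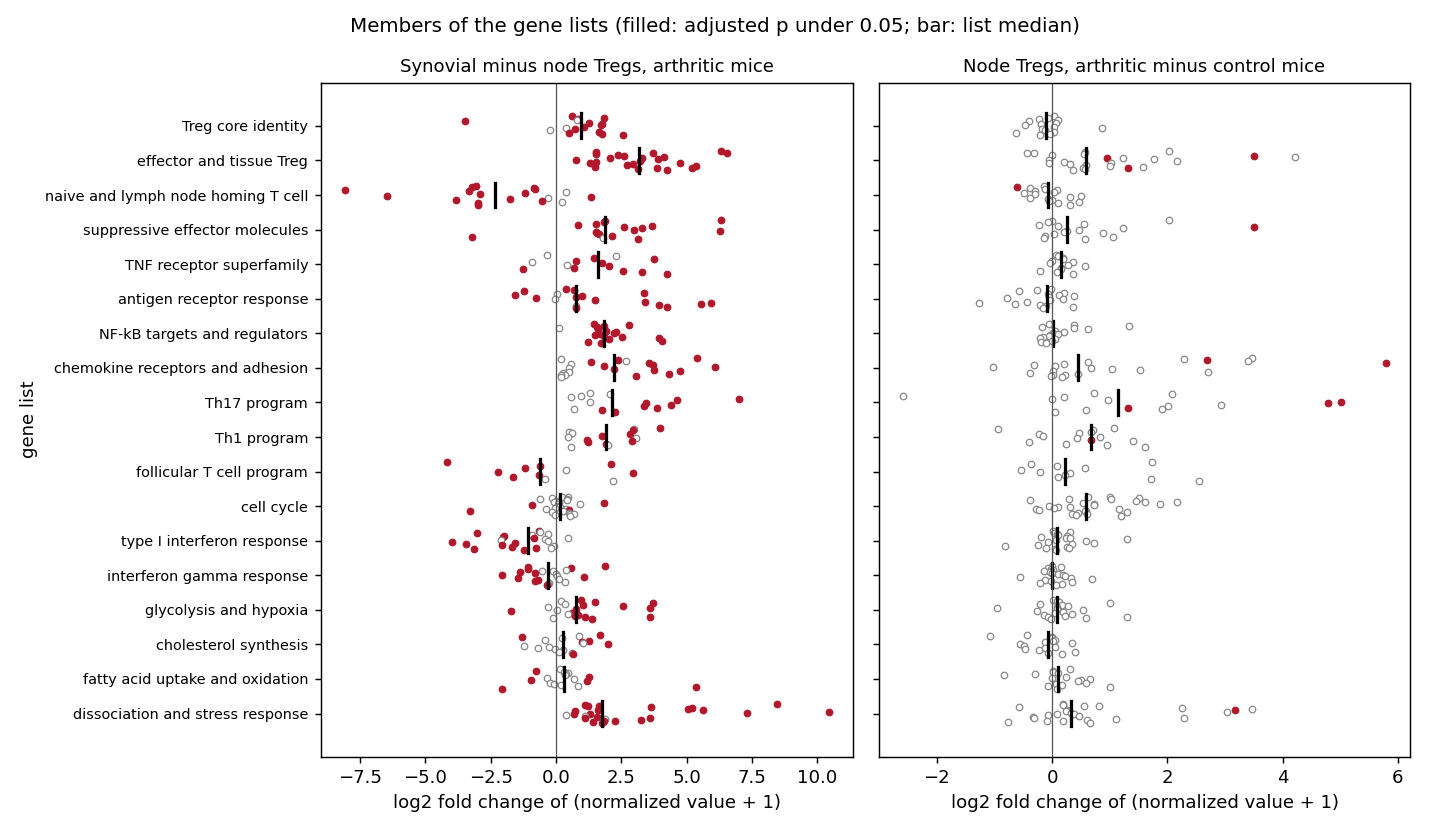
Log2 fold changes of the members of 18 program lists, a point per gene, filled where the adjusted p is under 0.05, with a bar at each list's median, for the tissue comparison (left) and the disease comparison (right). In the tissue comparison the medians run from -2.33 for naive and node-homing genes to 3.18 for effector and tissue Treg genes.

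Markers of other cells moved with tissue in part, but only members passing the filter on low values were tested. Among the untested ones, Clec9a and Itgax (dendritic), Mcpt4 and Cma1 (mast cell) and Krt5 (keratinocyte) had no read in synovium. Csf1r (macrophage) reached at most 1.10 there, while others had more, such as Siglech (dendritic) at 45.2 in synovial library 1. A rise of tested members alone therefore does not show that those cells were present. Of 6 dendritic cell markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0407, and adjusted p = 0.176 with an estimated correlation). Zbtb46 averaged 560.4 ± 40.2 in synovium against 22.4 ± 35.1, Xcr1 439 ± 119 against 21 ± 2.23 and Cd74 13059 ± 1488 against 4805 ± 437, while H2-Aa differed by -0.69 ± 0.68 (adjusted p = 0.471). The dendritic call was lost without synovial library 1 (adjusted p = 0.105) or arthritic node library 2 (adjusted p = 0.0568). Of 7 fibroblast markers tested, 6 were highest in synovial library 3: Col1a1 was 402 there against 38.6 and 1.17 in the other synovial libraries, and the 16 fibroblast markers made up 0.0244% of its normalized counts against 0.0048% and 0.00299%. That share was 0.00871% to 0.0126% in the 6 node libraries, where Prg4, at 1066 ± 106 in arthritic and 1236 ± 236 in control nodes, made up most of it. Exons of Prg4 overlap Tpr on the other strand, and the strand setting of the counting was not given, so its reads are uncertain. Without synovial library 3, 3447 genes changed, 3165 of them shared with the 3844 called with it. Among the 7 fibroblast markers tested Sparc rose and Prg4 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.444), and Sparc did not pass without synovial library 3 (adjusted p = 0.0946) or arthritic node library 1 (0.0835) or 2 (0.0816).

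Of 10 macrophage and monocyte markers, Cd14 rose and Apoe and Ctss fell (camera adjusted p = 0.52). Among 3 mast cell and basophil markers Kit and Hdc rose (camera adjusted p = 0.444), and among 3 keratinocyte markers Sfn and Perp rose and Krt10 fell (camera adjusted p = 0.423). Ltf rose and G0s2 fell among 3 neutrophil markers (camera adjusted p = 0.99). Another marker of that list, Acod1, stood in the data under its older name Irg1 and was missed by this test. Irg1 averaged 764 ± 204 in synovium with no read in arthritic nodes. Cd79b fell among 3 B and plasma cell markers (camera adjusted p = 0.266), Pecam1 fell as the only endothelial marker tested (camera adjusted p = 0.231), Mylpf fell among 2 muscle markers (camera adjusted p = 0.444) and Acp5 fell among 2 osteoclast and cartilage markers (camera adjusted p = 0.99). The erythroid and platelet marker tested (camera adjusted p = 0.625) and the 3 markers of CD8 T, NK and gamma delta T cells (camera adjusted p = 0.917) gave 0 calls. Several of these calls rest on few libraries. Hdc did not pass without synovial library 1 (adjusted p = 0.0808), 2 (0.0618) or 3 (0.0825) or arthritic node library 2 (0.102) or 3 (0.0594), nor Ltf without synovial library 1 (adjusted p = 0.0596) or 3 (0.0788) or arthritic node library 1 (0.101) or 3 (0.0976). Cd79b was lost without synovial library 1 (adjusted p = 0.0692) or arthritic node library 1 (0.0648) or 3 (0.0773), Mylpf without synovial library 1 (adjusted p = 0.0752) or 2 (0.0584) or arthritic node library 2 (0.0827) or 3 (0.0681), and Acp5 without arthritic node library 2 (adjusted p = 0.0525). DESeq2 did not call Cd14 (adjusted p = 0.182) or Ltf (adjusted p = 0.142). Adjusted over the list alone, these counts stayed the same except for 2 lower B and plasma cell markers, 1 lower mast cell marker and 1 higher osteoclast and cartilage marker.

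The largest rise by the fixed rule was that of Hspa1a, an inducible heat shock gene (chromosome 17, 34969190 to 34972156), at 11492 ± 2187 in synovium against 15.4 ± 14.2 in arthritic nodes (10.43 ± 0.99, adjusted p = 7.55e-06). Its near-identical neighbour Hspa1b can share its reads, so the split between them is uncertain. Ednrb, the endothelin receptor B gene (chromosome 14, 103814625 to 103844402), averaged 2824 ± 951 against 3.86 ± 4.43. Irg1, now named Acod1 (chromosome 14, 103046977 to 103056573), averaged 764 ± 204 in synovium with no read in arthritic nodes and was at least 282-fold higher. Under its newer name it is a member of the neutrophil marker list, which was tested without it. The type 2 cytokine gene Il5 (chromosome 11, 53720794 to 53725106) averaged 248 ± 160.2 and was at least 91.7-fold higher, Map9 was at least 112-fold and Kcna4 at least 110.1-fold higher. Cystm1 averaged 432 ± 212 against 0.582 ± 1.01, a ratio with a 95% counting interval of 199 to 5962. Atf3 rose by 8.46 ± 1.25, Sgip1 by 8.21 ± 1.15 and Calca, the calcitonin gene, by 7.77 ± 0.97.

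The largest fall was that of Dapl1 (chromosome 2, 59484653 to 59505020), at 0.391 ± 0.678 in synovium against 373 ± 177 in arthritic nodes, a ratio with a 95% counting interval of 174 to 38381. Slc16a5 was at least 72.5-fold, Art4 at least 64.5-fold, Tmem108 at least 21.8-fold, Ampd1 at least 21.3-fold and Tspan9 at least 19.4-fold lower, each with no read in synovium. Igfbp4 averaged 25.6 ± 28.7 against 1551 ± 313 and fell by 6.45 (SE 0.58). Treml2 fell by 6.89 (SE 0.52), Atp1b1 fell by 6.20 (SE 0.92) and the transcription factor gene Gata1 fell by 6.06 (SE 0.94).

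**Figure D2:**
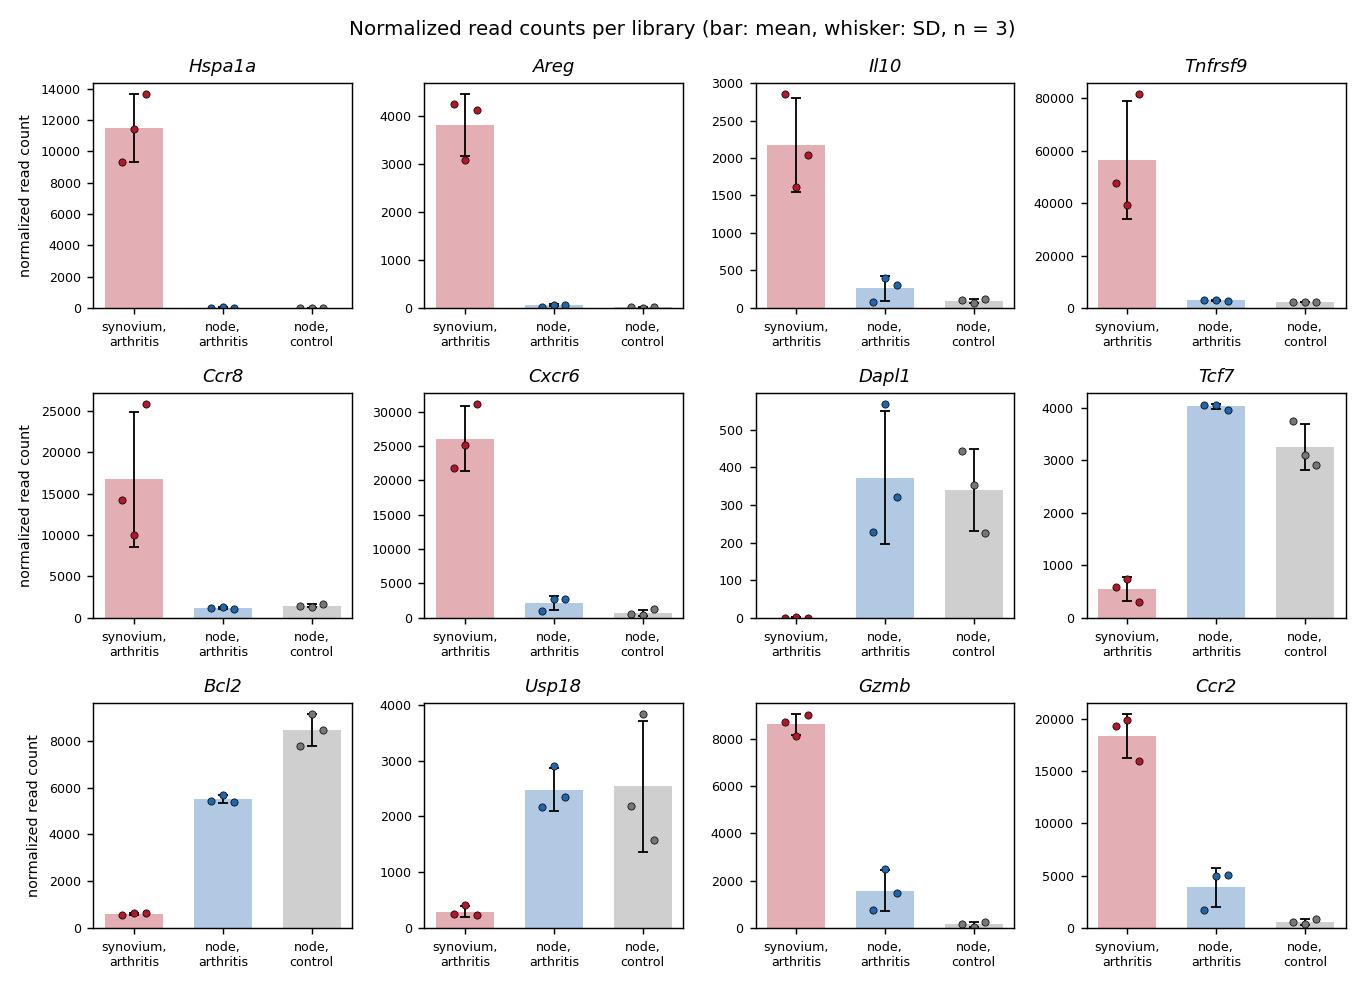
Normalized read counts of 12 genes on linear axes from 0, with a point per library, a bar for the mean and a whisker for the SD of the 3 libraries of each group. Hspa1a, Areg, Il10, Tnfrsf9, Ccr8, Cxcr6, Gzmb and Ccr2 lie higher in synovial than in node libraries, while Dapl1, Tcf7, Bcl2 and Usp18 lie lower.

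In all, 3844 of 11357 genes changed by limma, 2034 higher and 1810 lower in synovium. At least 4-fold changes numbered 937, with 624 higher and 313 lower. The libraries did not overlap in 5477 genes, or 48.2%, where chance gives 10%. Quantile normalization shifted the median of all genes to -0.12 and gave 1711 higher and 2344 lower calls, 42.2% higher against 52.9%. The authors' deposited table lists 4096 genes with an adjusted p under 0.05, 2242 higher and 1854 lower, and 3644 of these were also called by limma, all with the same sign.

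The disease comparison asked what differed between node Tregs of arthritic and control mice. Gzmb, which encodes granzyme B (chromosome 14, 56258838 to 56262260), averaged 1568 ± 873 against 144 ± 88 in controls, a rise of 3.50 ± 0.46 (adjusted p = 0.0121). Ccr2, a receptor for inflammatory chemokines (chromosome 9, 124101950 to 124113557), averaged 3886 ± 1865 against 585 ± 276 (2.68 ± 0.38, adjusted p = 0.0132). Socs3, a feedback inhibitor of cytokine signalling (chromosome 11, 117966079 to 117970047), averaged 1461 ± 324 against 308 ± 96.9 (2.26 ± 0.27, adjusted p = 0.0118). The 3 markers of CD8 T, NK and gamma delta T cells gave 0 calls, 1 adjusted over the list alone, with a median of 2.96, or 1.74 with genes at 0 set to their bound (camera adjusted p = 0.0179, and adjusted p = 0.276 with an estimated correlation). That call was lost without arthritic node library 3 (adjusted p = 0.103) or control library 2 (0.0658) or 3 (0.0752). Bcl2 was the 1 gene that fell among the 39 called, from 8464 ± 699 to 5508 ± 172 (-0.62 ± 0.11, adjusted p = 0.0278). By limma 39 genes passed, 38 higher and 1 lower in arthritic nodes, with 1031 at an unadjusted p under 0.05. The groups did not overlap in 14.9% of genes, where chance gives 10%. These calls rest on few libraries: without arthritic node library 2, 0 genes passed, and without library 3, 1 gene passed. Without control library 2 the count was 23 and without control library 3 it was 66. A fit of only these 2 groups called 0 genes, a fit without the variance trend 10, edgeR 37 (36 higher and 1 lower) and DESeq2 181 (141 higher and 40 lower). Weights per library and quantile scaling each gave 3 lower calls, and leaving out arthritic node library 1 gave 4. All genes named in this comparison lost their calls without arthritic node library 2, with adjusted p-values from 0.0825 for Gzmb to 0.242 for Il18r1, or without library 3, from 0.0595 for Id2 to 0.17 for Lgals3. Rora (adjusted p = 0.0793), Bcl2 and Il18r1 (both 0.0879) also lost theirs without arthritic node library 1. Without control library 1 those of Bcl2 and Il18r1 (both 0.0546), Lgals3 (0.0631), Icos (0.0865) and Rora (0.114) were lost. Without control library 2 the same genes, from 0.0537 for Lgals3 to 0.149 for Il18r1, and Lilrb4 (0.0555) and Gp49a (0.0584) did not pass, and without control library 3 Il18r1 (0.0557) and Bcl2 (0.0618) did not.

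Other genes named by the rule were Csf1, a macrophage growth factor gene, up by 2.27 ± 0.31, Lgals3, up by 2.54 ± 0.45, and Fosl2, up by 3.17 ± 0.47. Gp49a (3.04 ± 0.47) and Lilrb4 (2.45 ± 0.37) rose too, and their reads are uncertain because they are close paralogs under an overlapping annotation. The 10 macrophage and monocyte markers gave 0 calls, also adjusted over the list alone, with 7 of 10 positive and a median of 1.02, or 0.90 with genes at 0 set to their bound (camera adjusted p = 0.341). That list passed without arthritic node library 2 (adjusted p = 0.00174). Its member Apoe was 626, 130 and 710 in the arthritic and 237, 93 and 340 in the control node libraries.

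Of 24 effector and tissue Treg genes, 3 rose (Rora, Icos and Gzmb) and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 2e-08, and adjusted p = 0.276 with an estimated correlation). Of 14 Th17 genes, Il1r1, Rora and Il17re rose, 6 adjusted over the list alone (camera adjusted p = 1.01e-06, and adjusted p = 0.27 with an estimated correlation). Rora averaged 924 ± 149 in arthritic against 386 ± 150 in control nodes. Il1r1 was low, at 36.3 ± 16.9 against 0.304 ± 0.527, as was Il17re, at 32.0 ± 7.38 with no read in control nodes. The size of these latter changes depends on the pseudocount. Of 21 chemokine receptor and adhesion genes, 2 rose, among them Ccr2, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000606, and adjusted p = 0.394 with an estimated correlation). Il18r1 rose among 15 Th1 genes, 3 adjusted over the list alone (camera adjusted p = 0.0381, and adjusted p = 0.394 with an estimated correlation), and the Th1 call was lost without arthritic node library 2 (adjusted p = 0.216) or 3 (adjusted p = 0.0658) or control library 1 (0.0724), 2 (0.0763) or 3 (0.0737).

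Among 17 suppressive molecules Gzmb rose, 5 adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.349 with an estimated correlation), and the call was lost without control library 2 (adjusted p = 0.0763). Among 25 stress genes Fosl2 rose, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.457 with an estimated correlation). That call was lost without arthritic node library 1 (adjusted p = 0.247) or control library 2 (0.0645) or 3 (0.0752). The 28 cell cycle genes gave 0 calls, 0 adjusted over the list alone, and a camera adjusted p = 0.00168 (adjusted p = 0.642 with an estimated correlation), which was lost without arthritic node library 3 (adjusted p = 0.103) or control library 2 (0.42). Bcl2 fell among 18 naive and node-homing genes, 3 adjusted over the list alone (camera adjusted p = 0.225), and the 16 Treg core genes gave 0 calls, 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.14). The 22 type I interferon genes gave 0 calls, also adjusted over the list alone (camera adjusted p = 0.363). The other program and marker lists gave 0 calls, with camera adjusted p-values from 0.0867 for the antigen receptor response to 0.97 for mast cell and basophil markers. Adjusted over the list alone, 2 glycolysis and hypoxia genes and 1 NF-kB gene passed as higher and 1 antigen receptor response gene as lower. Without arthritic node library 2 the naive and node-homing list (adjusted p = 0.0406) and the follicular list (adjusted p = 0.014) passed.

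**Figure D3:**
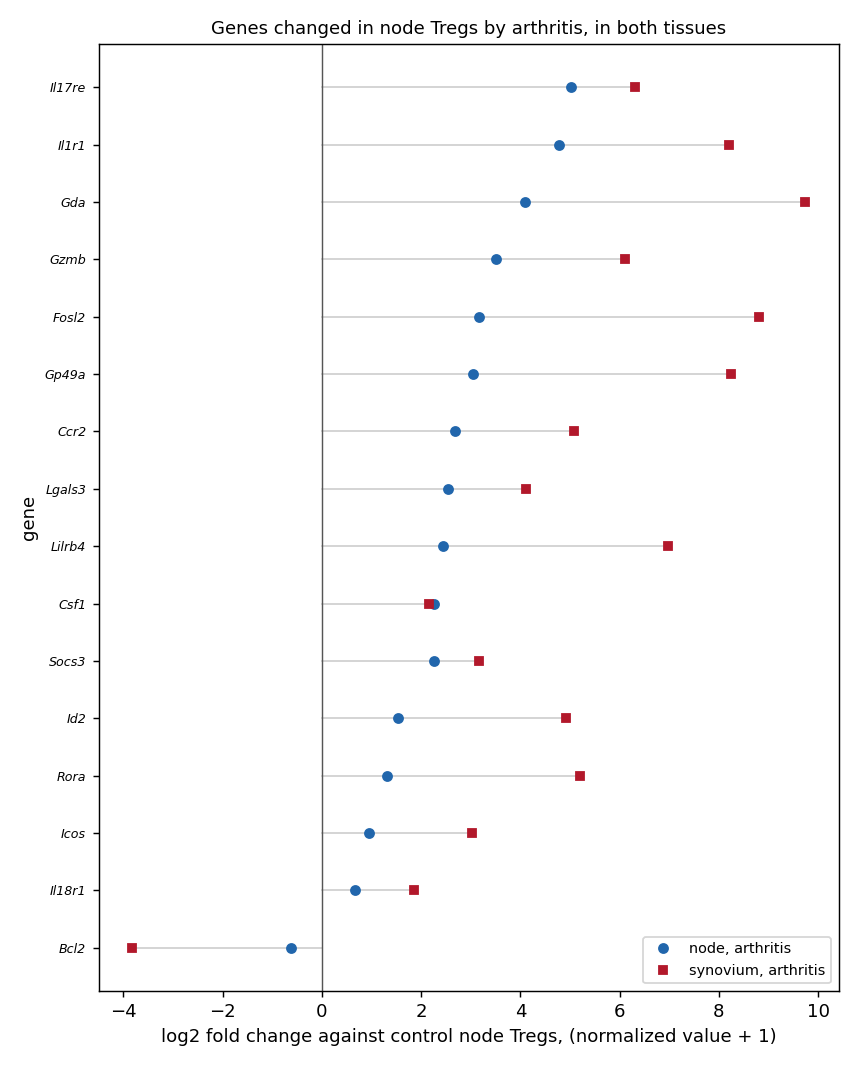
Log2 fold change against control node Tregs for the genes named here among the 39 called in the disease comparison, in arthritic node (circles) and in synovium (squares); values of genes with no read in controls depend on the pseudocount. The synovial value lies farther from 0 than the arthritic node value for each gene shown except Csf1.

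Of the 38 genes higher in arthritic nodes, 34 were higher again in synovium than in arthritic nodes and 0 were lower, where independent lists would share 6.81 and 6.06. Id2 averaged 1319 ± 51.8 in control nodes, 3891 ± 1001 in arthritic nodes and 40433 ± 7833 in synovium, and Icos averaged 5598 ± 1094, 10796 ± 1557 and 45557 ± 7525. Csf1 did not follow this order, at 440.4 ± 94.3 in arthritic nodes and 400.3 ± 9.45 in synovium. Both comparisons use the arthritic node libraries, with opposite signs. Simulated unchanged groups gave 0 higher disease calls in 50 draws, so they had no calls to share and set no baseline for the 34. The correlation of the fold changes across genes was 0.07, against -0.50 simulated, and the covariance was 0.0645 against -0.155, a difference of 0.22. As the simulated values show, noise in the 3 shared libraries pushes the fold changes in opposite directions, which works against the shared direction of the 34. Those libraries could not be split, so the size of the difference still depends on how well the simulation matched their noise.

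Synovial Tregs were also set against control node Tregs, where tissue and disease differ together. Hspa1a was at least 4076-fold higher in synovium, Ednrb at least 1002-fold, Calca at least 479-fold and Gda at least 313-fold, each with no read in control nodes. Trf, the transferrin gene, averaged 7141 ± 1600.4 against 15.2 ± 13.7. Art4 was at least 70.7-fold, Slc16a5 at least 53.1-fold and Tmem108 at least 35.7-fold lower, Treml2 fell by 7.13 (SE 0.52), and the counting interval of the ratio for Dapl1 was 159.9 to 35288. By limma 4551 genes changed, 2451 higher and 2100 lower, and the libraries did not overlap in 49.99% of genes, where chance gives 10%. Quantile normalization shifted the median to -0.13 and gave 1999 higher and 2747 lower calls, 42.1% higher against 53.9%.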

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

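No alternative in this part was chosen after its result was seen. In the tissue comparison 3844 genes passed, and all the alternatives gave counts within 1.5 times of that, from 3039 to 4598, except the rule of at least 2-fold, which leaves 2146 by construction. In the comparison differing in both, 4551 passed and 2646 did so at least 2-fold. Leaving out a library in turn gave 3039 to 3451 and 3823 to 4121 genes in these comparisons. The disease count of 39 was less stable. It was 10 without the mean-variance trend (8 shared), 0 in a fit of only the 2 groups compared, 181 with DESeq2 (141 higher and 40 lower, 38 shared), and 0 to 66 when a library was left out. The fit of 2 groups estimates the spread from fewer libraries, and DESeq2 made more false calls in the simulation, 32 of 167 against 9 of 118 for limma. For the other changes the cause was not tested.

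With the mouse number as a replicate block, 3776 genes passed in the tissue comparison, 3499 of them shared, and of the genes named there only Foxp3 and Tbx21 changed their call. The same 2 groups fitted without a block gave 3759 genes, and 2 named genes gained a tissue call there as well. Dropping the other group's libraries may therefore account for part of the change. In the other comparisons libraries share only a number. The block gave 0 genes in the disease comparison, where residuals of same-numbered libraries correlated at 0.00, 0.07 and 0.07 and 2 of 3 pairs matched best by number. A fit of these 2 groups without a block gave 0 as well, so the loss cannot be credited to the block. With the block 4204 genes passed in the comparison differing in both, with correlations of -0.02, 0.03 and 0.05 and 1 of 3 pairs. The Th1 list lost its disease call under the block (adjusted p = 0.0556).

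For the genes named in the text or taken by the rule, 2198 of 2279 values under the alternatives kept call and direction in the tissue comparison, with 71 calls lost and 10 gained. In the disease comparison 2178 of 2314 did, with 122 lost and 14 gained, and in the comparison differing in both 180 of 180 did. None turned direction. Of list members chosen after their values were seen, Pparg lost its tissue call with DESeq2 (adjusted p = 0.0659), Ldha and Hspa8 with quantile normalization (adjusted p = 0.134 and 0.612) and Cxcr5 without the mean-variance trend (adjusted p = 0.0853). With an estimated correlation 10 of the list calls in the tissue comparison, 8 in the disease comparison and 7 in the comparison differing in both were lost, and none turned direction. A pseudocount of 5 cost 1 list its disease call. Fry, which tests whether a list's genes move on balance one way without setting them against other genes, gave 6 more list calls in the tissue comparison and 7 more in the comparison differing in both. In the disease comparison 6 were lost with it: effector and tissue Treg (adjusted p = 0.0624), suppressive (0.106), chemokine receptor, Th1 and stress (each 0.133) and cell cycle (0.452). The naive, suppressive, NF-kB and stress lists kept their tissue call at an adjusted p = 0.0411. Depth limits the statements on low genes, since 3 reads equal a normalized value of 2.61 to 3.52.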

Other observations

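The tests of library depth, of handling, of read sampling and of the genes raised in arthritic nodes were chosen only after the results were seen, as were the genes of this paragraph. Several single genes differed in synovial Tregs. Penk is among the effector and tissue Treg genes counted above, and the others named here are not members of a tested set. Pcsk1, a prohormone convertase gene, averaged 1674 ± 993 in synovium against 17.3 ± 14.3 in arthritic nodes (7.08 ± 1.07, adjusted p = 0.000301), and Penk, which encodes proenkephalin, averaged 12064 ± 5059.8 against 1695 ± 159 (2.73 ± 0.29, adjusted p = 1.91e-05). Ramp1, a subunit of the receptor for the Calca product CGRP, rose by 1.64 ± 0.22 (adjusted p = 0.000103). The secreted trefoil factor gene Tff1 rose by 7.01 ± 1.04 (adjusted p = 0.000258), the chemokine gene Cxcl2 by 6.22 ± 0.89 (adjusted p = 0.000202) and the metallothionein gene Mt1 by 5.73 ± 0.76 (adjusted p = 0.000106). Lta, which encodes lymphotoxin alpha, averaged 102 ± 32.7 in synovium, 1119.6 ± 256 in arthritic nodes and 2049.7 ± 423 in control nodes, and fell by 3.47 (SE 0.26) between the tissues.

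Ribosomal protein genes were lower in synovium: 71 of 80 fell and 0 rose, with a median of -0.71 (-0.73 with TMM and -1.01 with quantile scaling). The hypothesis that they fell together was tested with camera. Its adjusted p was 0.3903 with an estimated correlation of 0.588, and 7.01e-19 with the preset one. Of 8 Gimap genes 0 rose and 3 fell, with a median of -0.27 (-0.80 with quantile scaling), and the adjusted p was 0.5272 with an estimated correlation of 0.675 and 0.0717 with the preset one. The bound set beforehand, an adjusted p of 0.05 or more, would have counted against a joint fall of either set. It was set aside for both after the results were seen, because correlations over 0.5 leave the test little power, so a joint fall stays open for both. Of 79 nuclear-encoded oxidative phosphorylation genes 6 rose and 10 fell, with a median of -0.06 (-0.27 with quantile scaling). Camera's adjusted p was 0.5272 with an estimated correlation of 0.113 and 0.116 with the preset one. By the bound set beforehand this counts against a joint fall of that set. However, camera with an estimated correlation gave 0.0545 even for the effector and tissue Treg list, where all 24 genes rose. A high value from it therefore does not exclude a joint fall.

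The 38 genes higher in arthritic than control nodes had a median tissue change of 2.231, where 1000 random sets of matched level gave -0.32 to 0.22 in their central 95% and at most 0.49. Of the 38, 35 were positive and 34 were called higher. A candidate explanation is that effector features gained in the arthritic node are raised further in the joint, which is a hypothesis found and tested on the same libraries. The node calls themselves rest on arthritic node libraries 2 and 3, without which 0 and 1 genes passed.

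Far fewer genes passed between arthritic and control nodes (39) than between synovium and node (3844). Without control library 1 the count was 29, which by the bound set beforehand counts against its spread having kept the count low. Leaving it out also shrinks the control group, and the count was 23 without control library 2 and 66 without library 3. An effect of its spread on the disease count itself is therefore not excluded. Node libraries held 0.9908 times the reads of synovial ones, which argues against lower depth, and edgeR called 37 genes, which argues against a loss of calls by the log scale test, while DESeq2 called 181, against 4188 in the tissue comparison. Both comparisons share an estimate of each gene's spread, so a wider spread between mice does not account for the difference in counts. Each gene also had the same standard error in both comparisons, so the gap reflects smaller measured fold changes between nodes than between tissues. Calls of at least 4-fold numbered 19 against 937. What made the node difference smaller was not tested.

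Stress and immediate-early genes rose in synovium. RNA of fibroblasts in synovial library 3 is unlikely to have carried them, because the median difference between library 3 and the mean of libraries 1 and 2 was 0.03884 for the stress list and 5.44 for the fibroblast markers, of which 6 of 7 were highest in library 3. In 21 of 25 stress genes every synovial library lay above every node library. Longer handling of paw tissue could give this, and so could the tissue itself. They cannot be told apart because tissue and handling differ together.

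Genes at substantial levels were at 0 in single libraries. Where the other 2 libraries of a group averaged 20 to 200, 756 of 31789 values (2.378%) were 0, against 1.53e-08% from Poisson sampling of reads, so read sampling alone does not account for them. The share ran from 1.43% in arthritic node library 1 to 4.86% in control library 1. Few starting molecules, each read many times after amplification, may account for it: the reads per molecule computed from the zeros were 10.8, 13.4 and 17.2 over bins of rising level, a ratio of 1.593. That lies between the bounds set beforehand, so it decides neither way, and no biological explanation was tested.

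The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. Every split but the real one mixes both groups on each side, so a real difference between the groups widens the spread there. Low counts in those splits are therefore no baseline for data without a difference. In the tissue comparison 1 split, the real one, gave as many genes (3844, highest other 0). In the disease comparison 1 split did (39, highest other 1), and in the comparison differing in both 1 split did (4551, highest other 0). For the tissue comparison, where numbers pair the libraries, 4 splits part all pairs, and the highest of the others was 0.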
